A study of Mus musculus with 6 samples.

How the data were processed

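RNA from 3 TA muscles and 3 primary tumours of mice was sequenced, and the labels state no treatment. The authors deposited 1 table of FPKM with a column for each library, per the file headers. The submitters' processing notes name CASAVA 1.9, BWA and the mouse build mm10 without a role, and the program that computed the FPKM, the gene annotation and the strandedness of the library are not given in the sources used here. The labels' extraction protocol describes Trizol RNA followed by primer extension on B2 SINE repeats and isolation of short products from a gel, which does not describe how values for all genes were made. How the library preparation affected the FPKM is therefore open. The table had 37170 lines, of which 20 repeated a gene identifier and were summed, leaving 37150 genes. Of these, 95.0% were found in GENCODE M21, which gave the biotypes and the mm10 positions. The symbols were those the authors deposited.

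The FPKM summed to between 1555640 and 3434190 per library, and mitochondrial transfer RNAs took 41.9% to 68.8% of that sum in muscle and 16.4% to 25.4% in the tumours. A unit relative to each library's total moves every other gene when such transcripts change, so 4 other scalings were computed. Read numbers were not given, so no counting interval is printed. Relative depth was read from the commonest ratio of short RNA values in each library to those in V235 muscle. It was 0.597, 0.460 and 0.943 for V235, V382 and V594 muscle and 0.498, 0.941 and 1 for V325, V382 and V594 tumour, relative to the deepest. Few rows held that ratio, from 27 of 679 compared in V382 tumour to 68 of 565 in V382 muscle, so these depths are rough. No 2 libraries held equal values. An exact 0 in a table without counts can be a failed estimate. In V594 muscle, 11 protein-coding genes were listed at 0 while both other muscle libraries had at least 20 FPKM. Some genes with such zeros are therefore given as values per library, Ckm and Atp2a1 among them.

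Groups came from the tissue labels and animal names from the titles. Libraries of 1 group carry different animal names, so p-values measure the spread between animals as far as the titles tell them apart. The comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with variances moderated by a trend on mean expression, for the 17121 genes with a mean of at least 1 FPKM over the 6 libraries, of which 12838 were annotated as protein-coding. A call is a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values. Paralogs and overlapping or antisense genes may share reads, since the counting is not given, which makes values of such genes uncertain, the globins, the myosins and overlapping mitochondrial genes among them. The 32 gene lists, which cover muscle programmes, metabolism, growth, signalling and other cell types, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Some genes stand on more than 1 list. A label check used the sex-linked genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty.

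The test, the lists, the alternatives and the rule for named genes were set before the data were examined, unless stated otherwise. The rule took the 8 largest increases and the 8 largest decreases among called genes with groups that did not overlap, 10 preset genes, from each list up to 4 called members with the largest change and at most 2 that did not pass, and the sex-linked genes. Since 5 of the 8 largest increases were listed at 0 in all muscle libraries, the 12 largest increases among genes above 0 in both groups were added. Members that did not pass are named for 9 lists only, and these lists were chosen after their values were seen. Tnnt3, Tpm1, Myh4, Aldoa and the mitochondrial genes listed at 0 in some muscle libraries, with mt-Nd3, were likewise named after their values were seen, as were the genes given for single tumours in the closing observations.

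Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, quantile, median-of-ratios and upper-quartile scaling, rescaling without genes over 0.5% of any library's sum, variances without trend or with robust moderation, a test against a log2 change of 1 (treat), the animal as a fixed or a random block, and leaving out each library. The list test under the random block used the ranked statistics of the blocked fit. Zeros set aside where another library had 1000 FPKM or more, protein-coding genes alone, and these with median-of-ratios factors were chosen after seeing the data. V382 and V594 named a library in both groups, and the correlation across genes of their deviations from the group means was 0.125 for V382 and 0.0687 for V594. For V235 muscle and V325 tumour it was 0.143, higher than for both, and whether these names stand for 1 animal is open, which would change the block. In the fixed block as fitted, V382 and V594 carry the contrast. The fit was tested on simulated data for the 17121 genes, with 200 genes changed in each of 10 draws of this comparison. It recovered 4.01%, 66.1% and 89.1% of genes changed by 1, 2 and 3 on the log2 scale, 6.20% of its calls were false, and it called 0 lists. These draws held no correlation between genes and no shift common to a group. They changed 200 genes where the data gave 11479 calls, so recovery and the share of false calls may differ in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.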

Results

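Transcript levels were measured by RNA sequencing in 6 mouse libraries, 3 from the tibialis anterior, a hindlimb muscle abbreviated TA, and 3 from primary tumours of a series titled as sarcoma. The muscle libraries carried the animal names V235, V382 and V594, and the tumour libraries the names V325, V382 and V594, so 2 animal names occurred in both tissues. V235 and V325 hold the same digits in another order, and the labels do not settle whether they name 1 animal, so they were treated as different animals. All 6 were labelled with strain PCG2 on a mixed C57BL/6 and CD1 background and with no treatment. The deposited values were FPKM, fragments normalised to transcript length and to the library's mapped fragments, for 37150 gene identifiers. Between 22191 and 22867 genes were above 0 in the muscle libraries and between 24413 and 25733 in the tumours. The number of reads is unknown. Relative depth, a rough value read from the commonest ratio of short RNA values between libraries, ran from 0.460 of the deepest library in V382 muscle to 1 in V594 tumour. Pearson's r of log2 values across genes, which are not independent replicates, was 0.904 to 0.915 between muscle libraries, 0.876 to 0.905 between tumours and 0.530 to 0.618 between the groups. Xist, transcribed from the inactive X chromosome, was 44.0 FPKM in V382 muscle and 338 in V382 tumour, and at most 0.833 in the other 4 libraries, while the Y-linked Ddx3y was at least 13.7 in those 4, so both libraries of V382 had the female and both of V594 the male pattern.

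The design compared the primary tumours with TA muscle. In the tumours most measured genes of the muscle contractile lists were lower than in muscle, and most measured genes of the Hedgehog list and all genes of the mitosis list were higher. Of these lists the fast-fibre list alone kept its call with an estimated correlation (adjusted p = 0.0206), which was lost for the slow-fibre (adjusted p = 0.332), Hedgehog (adjusted p = 0.442) and mitosis lists (adjusted p = 0.313). The Hedgehog target Gli1 was 0.826 ± 0.218 FPKM in muscle and 74.0 ± 28.2 in tumour (SD, n = 3 each). The growth factor gene Igf2 went from 18.3 ± 6.75 to 4763 ± 1997. Desmin (Des), an intermediate filament of muscle, went from 1172 ± 398 to 4.01 ± 2.02. Of 17121 genes with a mean of at least 1 FPKM, 9603 were higher and 1876 lower in tumour (limma, adjusted p under 0.05).

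This split changed with the scaling between libraries, and the median change over all tested genes was 1.06 on the log2 scale in the deposited values. Median-of-ratios factors lowered that median to 0.27 and gave 4974 higher and 3527 lower genes, and quantile normalization gave 4137 and 4174. The share of called genes that were higher was 83.7% as deposited, 78.2% after rescaling without the genes that dominate a library, 59.2% with upper-quartile factors, 58.5% with median-of-ratios factors and 49.8% after quantile normalization. The list median is therefore also given relative to all genes for the fast-fibre, Hedgehog, Wnt, Notch, interferon, YAP, immediate early, endothelial and pericyte lists. The medians of all lists are plotted with a dashed line at the median of all tested genes. Counts of rising and falling members and changes of single genes in the deposited values are not corrected for that median. In the deposited values the groups did not overlap for 12274 genes, 71.7% of those tested. Chance gives 10% only where no shift is common to a group. Median-of-ratios factors were 0.689 to 0.726 for the muscle libraries and 1.38 to 1.46 for the tumours, and such a shift can part the groups for unchanged genes. The share of genes without overlap was not computed under other scalings. In both V382 and V594, 11457 of the 11479 called genes (99.8%) differed between tumour and muscle in the called direction, and 83.7% did with median-of-ratios factors. These genes were called from the same libraries, so this share is a description and not an independent check.

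**Figure D1:**
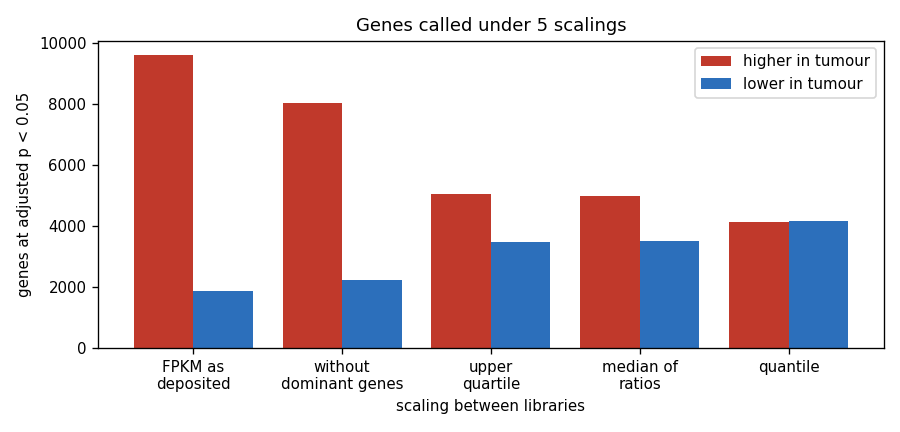
Bars give the number of genes at adjusted p under 0.05 (vertical axis, from 0) that were higher (red) or lower (blue) in tumour under 5 scalings between libraries (horizontal axis). The deposited FPKM gave 9603 higher and 1876 lower genes and quantile normalization 4137 and 4174.

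Muscle genes gave the largest decreases. The 8 largest were Myl1, Tnnc2, Tcap, Mylpf and Myh1, which encode parts of the fast-twitch contractile apparatus, Mb, which encodes the oxygen store myoglobin, and Cox6a2 and Cox8b, muscle isoforms of respiratory complex IV subunits. Myl1 (ENSMUSG00000061816, chromosome 1, 66924295 to 66945404; GENCODE M21 gene positions on mm10 are used throughout) went from 12996 ± 8489 to 11.1 ± 8.90 FPKM, a log2 change of -10.04 ± 0.71 (SE), limma adjusted p = 8.69e-05. Cox6a2 (ENSMUSG00000030785, chromosome 7, 128205435 to 128206387) went from 2373 ± 137 to 2.39 ± 0.770, a log2 change of -9.47 ± 0.24 (SE), limma adjusted p = 9.39e-06. The other 6 changed by -9.87 (Tnnc2) to -8.94 (Cox8b). Of 25 measured fast-fibre genes, 20 fell, 0 rose and 5 did not pass, and 20 fell when adjusted over the list alone. The median of the list was -7.46, or -8.52 relative to all genes (camera adjusted p = 2.59e-26, adjusted p = 0.0206 with an estimated correlation).

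The 5 fast-fibre genes that did not pass were Ckm, Atp2a1, Tnnt3, Tpm1 and Myh4, each listed at 0 in V594 muscle. Ckm, which encodes muscle creatine kinase, was 9236, 9876 and 0 FPKM in V235, V382 and V594 muscle and 7.27, 6.24 and 13.1 in the tumours. Atp2a1, which encodes the fast-fibre calcium pump, was 16749, 9516 and 0 in muscle and 9.83, 10.0 and 11.5 in the tumours. With such zeros set aside, a choice made after seeing the data, 25 of 25 members fell, with Myh4 set against V382 muscle alone, which is assumed to vary like the other libraries. The log2 changes were then -9.98 for Ckm (limma adjusted p = 2.56e-05) and -10.11 for Atp2a1 (limma adjusted p = 2.16e-05). Both also passed without V594 muscle (limma adjusted p = 0.000137 and 0.000133).

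Most measured slow-fibre, developmental and regulatory muscle genes were lower in the tumours, and none of these 3 lists kept its call with an estimated correlation. Of 13 slow-fibre genes, 8 fell and 1 rose, with log2 changes of -8.92 for Mybpc1 and -7.95 for Actn2 (camera adjusted p = 2.56e-07, adjusted p = 0.332 with an estimated correlation). With the fixed animal block, 5 fell and 0 rose, and 0 rose with median-of-ratios factors. The slow-fibre median in V594 muscle differed by -1.63 from the other muscle libraries on the log2 scale, and that in V382 muscle by 1.14. Of 10 embryonic and perinatal muscle genes, 7 fell and 2 rose. The embryonic and perinatal myosins Myh3 and Myh8 fell by 4.87 and 7.38 on the log2 scale, and the largest rise in that list was Igf2 (camera adjusted p = 1.20e-05, adjusted p = 0.0656 with an estimated correlation). Of 15 myogenic regulators, 11 fell and 1 rose (camera adjusted p = 5.17e-10, adjusted p = 0.0656 with an estimated correlation), and 0 rose with the fixed block, with median-of-ratios factors, or without V235 muscle, V594 muscle or V594 tumour. The lineage transcription factor Myod1 went from 17.6 ± 11.3 to 0.423 ± 0.427 FPKM (log2 change -3.57 ± 0.47 (SE), limma adjusted p = 0.000865) and Myog, which acts later in differentiation, from 3.87 ± 2.60 to 0.0243 ± 0.0243 (log2 change -2.12 ± 0.39 (SE), limma adjusted p = 0.00313). Des and Myf6 changed by -7.91 and -6.66. The satellite cell marker Pax7 stayed below the filter, with 0.179, 0.298 and 0.346 FPKM in V235, V382 and V594 muscle and 0, 0 and 0.0306 in V325, V382 and V594 tumour.

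Most measured genes of oxidative and muscle-type energy metabolism were lower in the tumours. Of 25 nuclear genes of oxidative phosphorylation, 24 fell, among them Cox7a1 (-8.68) and Cox5a (-3.03; camera adjusted p = 3.09e-21, adjusted p = 0.265 with an estimated correlation). Of 23 genes of the TCA cycle and fatty acid oxidation, 22 fell, led by Fabp3 (-7.17) and Cpt1b (-6.09), the fatty acid carrier of muscle and the entry step of mitochondrial fat oxidation (camera adjusted p = 5.53e-21, adjusted p = 0.0656 with an estimated correlation), and Idh2 did not pass, at 289, 124 and 146 FPKM in muscle and 143, 216 and 157 in the tumours. Of 18 muscle-type glycolysis and glycogen genes, 13 fell, with Eno3 and Pygm, muscle enolase and glycogen phosphorylase, at -7.88 and -6.96 (camera adjusted p = 3.80e-16, adjusted p = 0.0656 with an estimated correlation). Among 13 widely expressed glycolysis isoforms, 8 rose and 2 fell. Aldoc, Pgam1 and Eno1 rose by 4.85, 4.59 and 4.34, and the list as a whole was not called (camera adjusted p = 0.937, adjusted p = 0.958 with an estimated correlation). Median-of-ratios factors gave 4 falls in it. Of 15 hypoxia response genes, 11 rose, including Ero1l (4.04) and the glucose transporter gene Slc2a1 (3.29), with the list near the median of all genes (camera adjusted p = 0.241, adjusted p = 0.547 with an estimated correlation). With median-of-ratios factors 6 rose, and with the fixed animal block 7 did.

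Many mitochondrially encoded transcripts were listed at 0 in muscle libraries. The table lists mt-Co1, mt-Co3, mt-Atp6 and mt-Atp8, which encode subunits of complex IV and of ATP synthase, and the transfer RNA gene mt-Ts1 at 0 in all 3 muscle libraries. These 5 led the ranking of increases, so no fold is given. The tumours V325, V382 and V594 had 5010, 9467 and 6357 FPKM for mt-Co1, 6086, 13032 and 9330 for mt-Co3, 5893, 14618 and 8951 for mt-Atp6, 16613, 44305 and 27498 for mt-Atp8 and 119977, 240459 and 290799 for mt-Ts1. Of the 13 mitochondrial protein-coding genes, 4 were listed at 0 in V235 muscle, 6 in V382 muscle, 12 in V594 muscle and 0 in each tumour. The remaining gene in V594 muscle, mt-Nd3, was 14356, 29218 and 37695 FPKM in muscle and 1503, 3601 and 2865 in the tumours, a log2 change of -3.33 ± 0.52 (SE), limma adjusted p = 0.00165 (limma adjusted p = 0.0587 without the filter). With zeros set aside, a choice made after seeing the data, mt-Nd1, mt-Nd2, mt-Co2, mt-Nd5, mt-Nd6 and mt-Cytb were lower in the tumours than in V235 and V382 muscle, by log2 changes of -3.81 (mt-Nd2) to -2.07 (mt-Co2), with limma adjusted p from 0.00122 to 0.0129. For mt-Nd4 and mt-Nd4l the muscle value was then that of V235 alone, taken to vary like the other libraries, and their changes were -3.08 (limma adjusted p = 0.016) and -3.56 (limma adjusted p = 0.0117). As deposited, these 8 genes had changes in the opposite direction, 0.86 (mt-Nd2) to 6.24 (mt-Nd4), and none passed. Both mt-Nd4 and mt-Nd4l passed as higher with the fixed animal block (limma adjusted p = 0.0253 for both) and without V235 muscle (limma adjusted p = 0.000169 and 0.000213).

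Most measured Hedgehog pathway transcripts rose. Of 16 measured members, 13 rose, 0 fell and 3 did not pass, with 13 rising when adjusted over the list alone. The largest rise was Hhip, a ligand-binding target of the pathway (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006), from 1.34 ± 0.841 to 478 ± 203 FPKM (log2 change 7.66 ± 0.40 (SE), limma adjusted p = 3.28e-05). The receptor and target Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598) went from 1.62 ± 1.14 to 116 ± 52.8 (log2 change 5.47 ± 0.41 (SE), limma adjusted p = 0.000108), and Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974) changed by 5.28 ± 0.34 (SE), limma adjusted p = 6.06e-05. Foxf2 and Ccnd2 rose by 5.88 and 5.60. The co-receptor genes Gas1 and Cdon did not pass, with log2 changes of -0.97 and 0.51. With median-of-ratios factors Gas1 passed as lower, at -1.58 (limma adjusted p = 0.0302), and the change of Cdon, not past the test, was -0.12. The list's median was 3.54, or 2.48 relative to all genes (camera adjusted p = 0.00485, adjusted p = 0.442 with an estimated correlation).

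**Figure D2:**
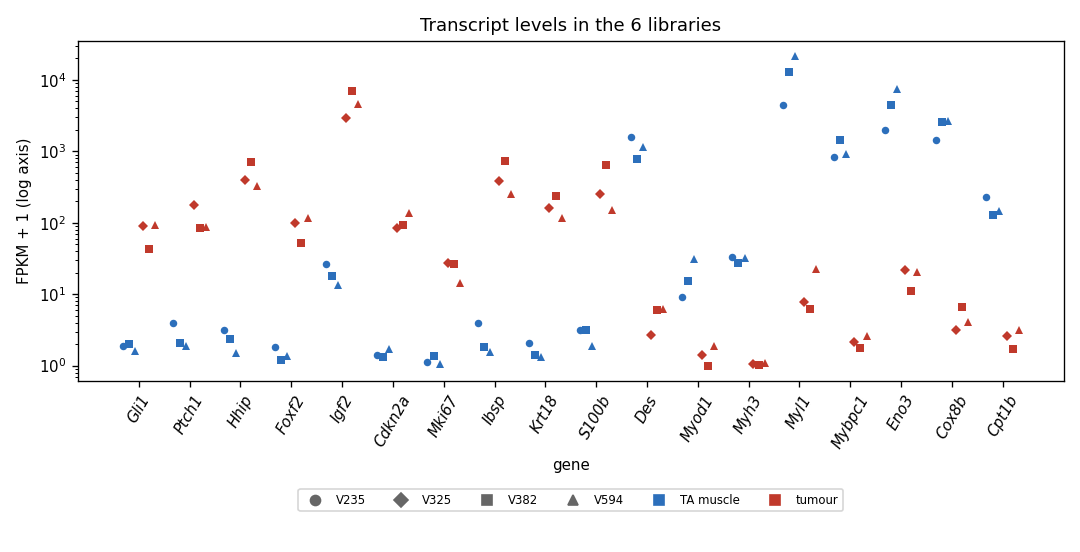
FPKM plus 1 (vertical axis, log scale) of 18 genes (horizontal axis) in each of the 3 TA muscle (blue) and 3 tumour libraries (red), with a marker shape per animal. Gli1 lies at 0.907, 0.992 and 0.579 FPKM in muscle and 89.3, 41.5 and 91.3 in the tumours, and every gene drawn has all tumour libraries on one side of all muscle libraries.

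Most measured growth and cell cycle genes were higher in the tumours in the deposited values, and none of their lists was called with an estimated correlation. Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816) had the largest increase among genes above 0 in both groups, a log2 change of 7.92 ± 0.41 (SE), limma adjusted p = 3.28e-05. It belongs to the imprinted growth genes, of which 13 of 14 rose, including Nnat (6.17), Plagl1 (4.86) and Peg3 (3.77; camera adjusted p = 0.0257, adjusted p = 0.313 with an estimated correlation), against 9 with median-of-ratios factors and 8 with quantile normalization. All 25 mitosis genes rose, with Top2a at 6.21 and Cdk1 at 5.77 (camera adjusted p = 2.56e-07, adjusted p = 0.313 with an estimated correlation), and 24 rose with median-of-ratios factors. Mki67, a marker of cycling cells, went from 0.182 ± 0.164 to 21.7 ± 7.24 FPKM (log2 change 4.21 ± 0.30 (SE), limma adjusted p = 8.67e-05). All 21 DNA replication genes rose, with Rrm2 at 4.61 and Mcm6 at 4.44 (camera adjusted p = 3.48e-06, adjusted p = 0.265 with an estimated correlation). Of 19 p53 targets and CDK inhibitors, 16 rose (camera adjusted p = 0.0551, adjusted p = 0.459 with an estimated correlation). That list was called with median-of-ratios factors (camera adjusted p = 0.0174, 10 rising and 2 falling), with the animal as a random effect (camera adjusted p = 0.0152) and without V235 muscle (camera adjusted p = 0.0446), V594 muscle (camera adjusted p = 0.0441) or V382 tumour (camera adjusted p = 0.0414). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) went from 0.480 ± 0.197 to 103 ± 28.0 FPKM (log2 change 6.11 ± 0.24 (SE), limma adjusted p = 1.79e-05), and the apoptosis gene Bax rose by 3.37. Of 20 ribosome biogenesis genes and MYC targets, 13 rose, among them Nop58 (2.62) and Fbl (2.49), and the list lay near the median of all genes (camera adjusted p = 0.238, adjusted p = 0.752 with an estimated correlation), with 5 rising under median-of-ratios factors.

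Members of other signalling lists rose, while none of these lists was called as a whole in the deposited values. Of all 17121 tested genes 9603 were called higher, so counts of rises alone do not set a list apart. Relative to all genes the list medians were 1.05 for Wnt targets and 0.79 for Notch pathway genes. They lay near that of all genes for interferon response (0.105), YAP targets (-0.17) and immediate early genes (-0.16). Of 8 Wnt targets, 7 rose, led by Tcf7 (6.42), Notum (4.26) and Lef1 (4.13; camera adjusted p = 0.107, adjusted p = 0.641 with an estimated correlation). With the fixed animal block 3 Wnt targets rose and with quantile normalization 4, and the list was called with median-of-ratios factors (camera adjusted p = 0.0162) and without V382 tumour (camera adjusted p = 0.0243). Of 13 Notch pathway genes, 10 rose, including Hey1 (3.62) and Notch2 (3.07; camera adjusted p = 0.159, adjusted p = 0.459 with an estimated correlation), against 5 with the fixed block and 6 with median-of-ratios factors. Of 12 YAP targets, 6 rose and 2 fell, with Tead2 at 4.76 and Ankrd1 at -4.35 (camera adjusted p = 0.532, adjusted p = 0.752 with an estimated correlation). With the fixed block, without V594 muscle or without V594 tumour 3 YAP targets rose, and with median-of-ratios factors 2 rose and 3 fell. Without V235 muscle, V594 muscle, V325 tumour or V382 tumour 1 YAP target fell. Of 10 interferon response genes, 6 rose, led by Bst2 (2.93; camera adjusted p = 0.469, adjusted p = 0.752 with an estimated correlation), against 1 with median-of-ratios factors, and with quantile normalization 1 rose and 2 fell. Of 13 immediate early genes, which also respond to sample handling, 6 rose and 2 fell (camera adjusted p = 0.469, adjusted p = 0.752 with an estimated correlation), and 1 rose with the fixed block. With median-of-ratios factors 3 immediate early genes rose and 3 fell, and with quantile normalization 2 rose and 3 fell, while 1 fell without V382 muscle, V594 muscle, V325 tumour or V382 tumour. The median of the immediate early genes in V382 muscle lay 0.94 above the other muscle libraries on the log2 scale.

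Several lineage markers foreign to adult muscle fibres were high in the tumours. Of 12 cartilage and bone markers, 9 rose (camera adjusted p = 0.0472, adjusted p = 0.313 with an estimated correlation). Ibsp, which encodes bone sialoprotein (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469), went from 1.46 ± 1.35 to 456 ± 247 FPKM (log2 change 7.53 ± 0.51 (SE), limma adjusted p = 7.20e-05), and the transcription factor genes Sox9 and Sp7 rose by 5.09 and 4.92. That list was not called with the fixed animal block (camera adjusted p = 0.0749) or without V235 muscle (camera adjusted p = 0.0786) or V594 muscle (camera adjusted p = 0.0521). Of 9 epithelial markers, 6 rose, including the keratin genes Krt18 (6.73) and Krt8 (5.63) and Epcam (4.99; camera adjusted p = 0.0514, adjusted p = 0.459 with an estimated correlation). The epithelial list was called with median-of-ratios factors (camera adjusted p = 0.00278), with the animal as a random effect (camera adjusted p = 0.00741) and without V382 muscle (camera adjusted p = 0.0424), V325 tumour (camera adjusted p = 0.049), V382 tumour (camera adjusted p = 0.0273) or V594 tumour (camera adjusted p = 0.00922). Of 7 Schwann cell markers, S100b alone rose, by 6.78 (camera adjusted p = 0.469, adjusted p = 0.659 with an estimated correlation), and 2 rose without V382 muscle or without V382 tumour. Median-of-ratios factors gave 1 fall among the Schwann cell markers, and quantile normalization 2.

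The other largest increases among genes above 0 in both groups, a ranking extended after the zeros were seen, were Gal, Gpc3, Napsa, Krt17, Wfdc2, Htr3a, Psrc1, Ccnd1 and Sct, with log2 changes from 7.42 to 6.96. Gal encodes the neuropeptide galanin and went from 1.12 ± 0.897 to 347 ± 63.3 FPKM (log2 change 7.42 ± 0.33 (SE), limma adjusted p = 2.28e-05). Gpc3, a cell surface glypican gene, went from 6.22 ± 2.98 to 1262 ± 776 (log2 change 7.38 ± 0.52 (SE), limma adjusted p = 8.20e-05). Sct encodes the hormone secretin and went from 0.391 ± 0.247 to 171 ± 18.3 (log2 change 6.96 ± 0.21 (SE), limma adjusted p = 1.19e-05). Ccnd1, a G1 cyclin gene, was 1765, 222 and 1244 FPKM in V325, V382 and V594 tumour and 9.06, 5.49 and 2.89 in muscle.

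Most matrix genes and macrophage markers were higher in the tumours, although neither list was called as a whole in the deposited values, and V382 muscle stood apart from the other muscles in both. Of 24 extracellular matrix genes, 19 rose (20 when adjusted over the list alone), among them Vcan (6.32), Mmp14 (4.81) and Timp1 (4.36; camera adjusted p = 0.131, adjusted p = 0.752 with an estimated correlation). Col1a2 and Lum did not pass, and Col1a2 was 2.59, 119 and 12.7 FPKM in V235, V382 and V594 muscle and 70.5, 144 and 373 in V325, V382 and V594 tumour. The matrix list's median in V382 muscle lay 2.29 on the log2 scale above the other muscle libraries, and without that library 21 members rose and the list was called (camera adjusted p = 0.00113). Without V382 muscle both passed, Col1a2 at 4.49 (limma adjusted p = 0.00725) and Lum at 3.39 (limma adjusted p = 0.0206), and Lum passed with the animal as a random effect (limma adjusted p = 0.0469). With the fixed animal block 4 matrix genes rose, and with median-of-ratios factors 12, where the list was called (camera adjusted p = 0.00719). Dcn passed as lower with median-of-ratios factors, at -2.58 (limma adjusted p = 0.0163). Of 17 macrophage markers, 15 rose, led by Laptm5 (4.79) and C1qc (3.34), while Mrc1 and Ptprc did not pass, with log2 changes of 1.60 and 0.94 (camera adjusted p = 0.111, adjusted p = 0.752 with an estimated correlation). Without V325 tumour both passed, at 2.27 (limma adjusted p = 0.0253) and 1.28 (limma adjusted p = 0.0218), and Mrc1 also passed without V382 muscle (limma adjusted p = 0.0436) and with the fixed animal block (limma adjusted p = 0.0332) or the random block (limma adjusted p = 0.0402), and Ptprc with the random block (limma adjusted p = 0.0352). V382 muscle lay 1.49 above the other muscle libraries for this list, which was called without that library (camera adjusted p = 0.0113), without V325 tumour (camera adjusted p = 0.0147), with the fixed animal block (camera adjusted p = 0.0106) and with median-of-ratios factors (camera adjusted p = 0.0174, 9 rising). The 3 measured lymphocyte markers, Cd79a, Lck and Cd4, rose by 4.43, 3.66 and 2.10 (camera adjusted p = 0.115, adjusted p = 0.371 with an estimated correlation), and that list was called with median-of-ratios factors (camera adjusted p = 0.0285). Of 5 neutrophil markers, Mmp9 alone rose (camera adjusted p = 0.635, adjusted p = 0.796 with an estimated correlation). Its limma adjusted p was 0.076 with the animal as a fixed term, while the call stood with it as a random effect, and 0.0924 under quantile normalization, where 0 neutrophil markers rose. Without V382 tumour or with the random block 2 neutrophil markers rose.

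The endothelial and adipocyte lists were called lower relative to other genes in the deposited values, and neither kept its call with an estimated correlation. Members of both lists changed in both directions. Most fibro-adipogenic and tendon markers did not pass the test. Of 14 endothelial markers, 2 rose and 2 fell, with Cdh5 at 1.75 and the receptor gene Tek at -0.96, a call that was absent with the animal as a fixed term (limma adjusted p = 0.09) and present with it as a random effect. Pecam1 and Kdr did not pass, with log2 changes of -0.69 and -0.66, and with median-of-ratios factors both passed as lower, at -1.62 (limma adjusted p = 0.0195) and -1.52 (limma adjusted p = 0.00892). The list's median of -0.41 lay -1.47 from that of all genes (camera adjusted p = 0.00326, adjusted p = 0.459 with an estimated correlation), and median-of-ratios factors gave 9 falls and 1 rise. With the animal as a random effect the list was not called (camera adjusted p = 0.0827), and without V325 or V382 tumour 1 member fell. Of 10 pericyte and smooth muscle markers, 5 rose and 2 fell, with Cspg4 at 4.43 and Acta2 at 2.99, and the list's median lay -0.10 from that of all genes (camera adjusted p = 0.52, adjusted p = 0.752 with an estimated correlation), against 3 and 0 with the fixed animal block. Of 14 fibro-adipogenic and tendon markers, 3 rose, including Pdgfra (3.13), and the others did not pass, among them Thbs4 (-1.81) and Clec3b (-1.65), which passed with the fixed animal block (limma adjusted p = 0.0307). That list was called lower relative to other genes (camera adjusted p = 0.0297, adjusted p = 0.641 with an estimated correlation), not so without V382 muscle (camera adjusted p = 0.345), where its median lay 2.03 above the other muscle libraries, with median-of-ratios factors (camera adjusted p = 0.214), with the animal as a random effect (camera adjusted p = 0.196) or without V325 tumour (camera adjusted p = 0.0824). Of 10 adipocyte markers, 3 fell and 2 rose, with Car3, also abundant in muscle, at -8.04, Plin4 at -5.53 and Plin1 at 3.07 (camera adjusted p = 0.00256, adjusted p = 0.371 with an estimated correlation), and 7 fell with median-of-ratios factors or without V382 tumour. The adipocyte list was not called with the animal as a random effect (camera adjusted p = 0.097). None of the 5 erythrocyte markers passed, although the list was called lower (camera adjusted p = 0.034, adjusted p = 0.547 with an estimated correlation), and the call was absent with the animal as a fixed term (camera adjusted p = 0.588) or a random effect (camera adjusted p = 0.226), with median-of-ratios factors (camera adjusted p = 0.098) and without V235 muscle (camera adjusted p = 0.0892), V382 muscle (camera adjusted p = 0.0627) or V325 tumour (camera adjusted p = 0.109). Hba-a1, an alpha-globin gene, was 958, 653 and 151 FPKM in V235, V382 and V594 muscle and 60.9, 653 and 183 in V325, V382 and V594 tumour.

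**Figure D3:**
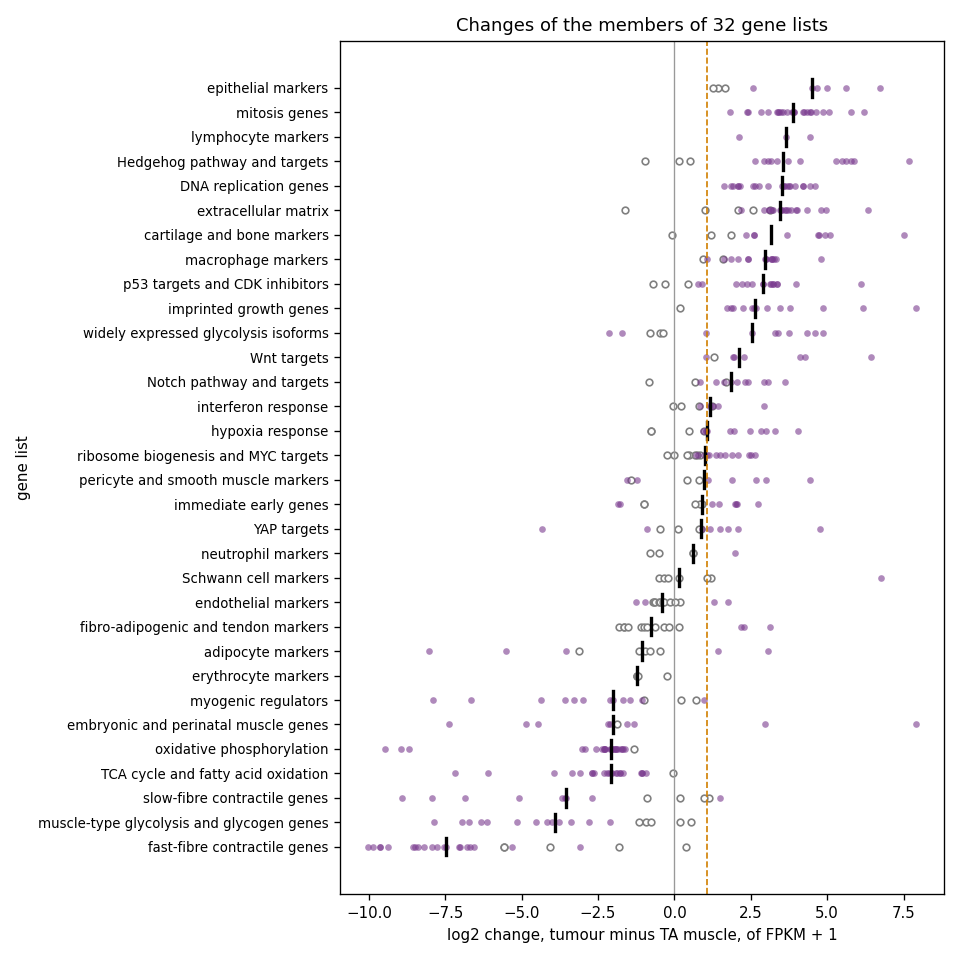
Log2 change of FPKM plus 1, tumour minus TA muscle (horizontal axis), of each measured member of 32 gene lists (vertical axis), with filled points for genes past adjusted p 0.05, open points for the others, a black bar at each list's median, a grey line at 0 and a dashed line at the median of all tested genes, 1.06. Fast-fibre genes have the lowest median, -7.46, and epithelial markers the highest, 4.51.

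Of the 32 lists, camera with a preset correlation between genes called 16, and with a correlation estimated from these 6 libraries the fast-fibre list alone kept its call. When the libraries were split into 3 and 3 in ways that mixed tumour and muscle, camera with the preset correlation called 11 to 19 lists. Limma called up to 3 genes in these splits. The number of lists called with the preset correlation therefore does not set the real groups apart from mixed ones. Adjusted over the list alone, counts differed from those over all genes for extracellular matrix (20 higher and 0 lower), interferon response (5 higher and 0 lower), immediate early genes (5 higher and 2 lower) and fibro-adipogenic and tendon markers (2 higher and 0 lower), and for no other list. For YAP targets (0.89), immediate early genes (0.89), neutrophil markers (0.60), pericyte and smooth muscle markers (0.96) and Schwann cell markers (0.16), camera pointed lower relative to other genes while the list's median lay above 0. Exact two-sided permutation of 3 against 3 libraries cannot give a p under 0.1.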

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

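The fits limited to protein-coding genes or with zeros set aside were chosen after seeing the data. Against 9603 higher and 1876 lower genes as deposited, quantile normalization gave 4137 and 4174, median-of-ratios factors 4974 and 3527, and upper-quartile factors 5063 and 3486. Protein-coding genes with median-of-ratios factors gave 4404 and 3001, and treat gave 4197 and 840 by its stricter construction. The rescaled fits lowered the median change over all genes from 1.06, which moves calls from higher to lower. It became 0.034 with quantile normalization, 0.27 with median-of-ratios and 0.28 with upper-quartile factors, and 0.25 with protein-coding genes and median-of-ratios factors. Which scaling is nearest to the RNA content of the tissues was not tested. Of genes called both ways, 45 had opposite directions under quantile normalization. Leaving out each library gave 8263 to 9387 higher and 1571 to 1828 lower genes and 16 to 19 lists. Camera called 16 lists, 1 with an estimated correlation, and fry, which does not compare a list with other genes, called 26. The animal block gave 6612 higher and 1368 lower genes and 15 lists as a fixed term, and 10163, 2037 and 14 as a random effect, whose estimated correlation within an animal was 0.333. The share of called genes with the called direction in both animals was 83.7% with median-of-ratios factors. Over 152 single genes and 3323 pairs of gene and setting, 3190 kept direction and call, 77 lost the call, 43 gained it and 13 changed direction. Tnnt3, Tpm1, Myh4, Aldoa, mt-Nd3 and the mitochondrial genes at 0 in only some muscle libraries were not among these genes. Without V594 muscle some of them changed direction, such as Aldoa from 0.53 to -4.00, and others, such as Tnnt3, kept it. The change of Cdon was -0.70 under quantile normalization, -0.12 with median-of-ratios factors, -0.11 with upper-quartile factors and -0.12 with protein-coding genes and median-of-ratios factors. The Idh2 log2 change was 0.45 with the fixed block, 0.082 with the random block, and -0.28 to 0.33 with each library left out in turn, positive without V235 muscle, V325 tumour (0.081) or V594 tumour (0.016). Irf7, called as higher in the deposited values, was -0.029 and Ptprc -0.15 under quantile normalization, and Hba-a2 was 0.17 and Hba-a1 0.14 with the fixed block, and the cause was not tested. These single genes leave out members that did not pass in most lists, a choice made after values were seen, and with up to 2 such members from every list, 188 genes gave 4095 pairs, of which 3844 kept direction and call, 77 lost the call, 124 gained it and 50 changed direction, 1 of them in a called gene, Irf7. Depth is unknown, which leaves the precision of low values open.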

Other observations

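Single tumours differed in groups of genes, given here as values of 1 library against the other tumours with no test. In V382 tumour the median log2 difference was -1.06 for Wnt targets, -1.17 for epithelial markers, 1.27 for adipocyte markers, 2.57 for erythrocyte markers and 0.99 for macrophage markers. In V325 tumour it was -1.33 for macrophage markers, -1.47 for fibro-adipogenic and tendon markers and -2.79 for erythrocyte markers. In V594 tumour it was 1.23 for matrix genes, 1.13 for epithelial markers, 1.01 for lymphocyte markers and 1.02 for neutrophil markers. Cfd, which encodes adipsin, was 0.173, 30.9 and 0.108 FPKM in V325, V382 and V594 tumour and 15.3, 39.2 and 40.1 in V235, V382 and V594 muscle. Adipoq, the gene of the fat hormone adiponectin, was 0.114, 4.18 and 0.0427 in the tumours.

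Whole-chromosome gains or losses were tested as a hypothesis for differences between tumours. The largest median difference of an autosome, 1 tumour against the others, was 0.186 on the log2 scale, for chromosome 13 in V382 tumour. It lay between 0.15, under which every autosome was to stay without such a change, and 0.3, which a gain or loss was to reach, so the hypothesis stays open.

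The tests of the zeros, of the matrix genes, of the remaining muscle transcripts and of splits for gene lists were chosen after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real split (11479 genes, highest other 3) and 3 as many called lists (16 lists, highest other 19), the real split included. These 10 splits are too few for a share under 0.05.

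In V594 muscle, abundant transcripts such as Ckm, Atp2a1, Tnnt3 and Aldoa were listed at 0. A loss of fast-fibre expression in that animal is argued against, since 20 fast-fibre genes above 0 in every muscle library had a median log2 difference of 0.55 against the other muscles (range -0.87 to 1.49). Failed estimates at whole loci may be the source. The test of this took nuclear genes only and left out the 6 mitochondrial protein-coding genes among the zeros. Of the nuclear zeros with an abundant neighbour within 10 kb, 100%, 2 of 2 genes, had such a neighbour at 0, against 0.358% of 558 other nuclear genes. With 2 genes this stays open.

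V382 muscle had high matrix transcripts. Tumour cells in that piece of muscle were tested with the 12 genes with the largest increase in tumours. Their median log2 difference there against the other muscles was -0.023 (range -0.54 to 0.80). The ranking of these genes used V382 muscle itself, which favours genes that are low there, so this test cannot exclude tumour cells. Tendon or fascia in the piece may be a source, since the fibro-adipogenic and tendon list, which shares no gene with the matrix list, had a median difference of 2.03, and 14 of its 14 members were highest in V382 muscle. Its members Thbs4 and Fmod were 8.29, 77.2 and 13.7 and 3.59, 79.7 and 1.06 FPKM in V235, V382 and V594 muscle. The sex of the animal, by Xist the 1 female among the muscles, stays open and was not tested.

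Fast-fibre transcripts in the tumours stood at a median of 0.189%, 0.163% and 0.259% of the muscle level in V325, V382 and V594. As an explanation, a constant small share of muscle tissue in the tumour pieces could leave all of them at 1 ratio. Of 20 genes, 1 gene, Cacna1s, lay over 10 times the median ratio in all 3 tumours, fewer than the 2 that would have argued against such a share. The ratios were unequal, from 0.0515%, 0.0405% and 0.164% for Myl1 through 0.756%, 0.855% and 1.31% for Tpm2 and 1.63%, 4.34% and 2.17% for Tnni2 to 15.2%, 6.54% and 13.8% for Cacna1s in V325, V382 and V594, where a constant share predicts 1 ratio. The fibre types of any muscle in the pieces are unknown, so the source of these transcripts stays open.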
